A study of Arabidopsis thaliana with 8 samples.

How the data were processed

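Polyadenylated RNA of whole 10-day-old seedlings grown in soil was sequenced for 2 libraries of each of 4 groups, per the labels: Col-0 wild type and mem1-1, each untreated or given 200 ppm MMS. Reads were aligned to the TAIR10 genome with HISAT2 2.1.0 and assigned to genes with featureCounts 1.6.3, per the submitters' processing notes. The deposited values are expected counts per gene: most are whole, and 2.74 to 3.28% of the genes above 0 in a library hold fractions. Fractions can arise where reads are shared between near-identical genes. Genes with fractions are described below as sharing reads, although how reads were split is not stated. The labels give no normalization of these counts, and neither the strand setting nor the counting of read pairs is stated. Whether genes on opposite strands were told apart is therefore not known.

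Whole counts had been assumed before the data were examined, so the expected counts were rounded, which changed the total of a library by at most 303 reads. Each file lists 37869 genes. Of these, 37573 matched a reference table of assembly TAIR10.1, which was used for names. Its coordinates were used only to find which genes overlap and which features lie within 10000 bases of a long ribosomal RNA gene, and none is printed. The 296 unmatched genes are organelle genes and all stood at 0. No gene in the table is classed as a transposable element gene, so the planned test of that class was not run. Genes with fractional counts, which include the RBCS, LHCB2, BIP and PHT1;1 families, are uncertain, and so are near-identical families such as PDF1.2 and GSTF6 with GSTF7. Genes overlapped by another gene over at least 90% of their exons stood at 0 in 528 of 561 cases (94.1%), against 3002 of 23860 (12.6%) of genes overlapped under 10%. Among list members SMR5, MYC2 and F3H are overlapped to that extent.

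Counts were normalised by TMM (factors 0.730 to 1.19), filtered with filterByExpr and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, 4 group means and all 8 libraries. The 20222 genes kept were tested in 5 comparisons: mem1 against wild type untreated, mem1 against wild type under MMS, MMS against untreated in wild type, MMS against untreated in mem1, and the interaction. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and the threshold was 0.05. The common dispersion was 0.000445, a biological coefficient of variation of 2.11%. Values in CPM (counts scaled to a library of 1000000) were computed with TMM library sizes and fold changes with a prior count of 0.125, and their standard errors come from the information matrix of the fit and the quasi-likelihood dispersion, with none given where a compared group has 0 reads. For 10 genes with very high counts, 6 of them ribosomal RNA repeat features and the others RBCS1A, RBCS3B, RCA and LHCB1.3, the fitted dispersion was so low that edgeR approximates the deviance badly. Their adjusted p-values are unreliable and their standard errors are not given. A refit with the dispersion held just above that limit, made after this was seen, called 7572, 10469, 13071, 12985 and 8957 genes and changed 5, 5, 4, 3 and 0 calls. The only list member among these was LHCB1.3, which passed for MMS in mem1 in the refit (adjusted p = 0.0119, against 0.158). A gene at 0 reads in a group is given a bound computed against a floor of 3 counts per library, which is 0.230, 0.170, 0.230 and 0.189 CPM in untreated wild type, treated wild type, untreated mem1 and treated mem1. With 1 to 3 reads in a group a ratio with its 95% counting interval is given, computed from the summed reads of both libraries of each group. Intervals and floors cover counting error only.

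The design, 19 gene lists and the rule for naming genes were written before the data were examined. The lists were drawn up from general knowledge: photosynthesis, root markers, floral markers, jasmonate, salicylic acid and pathogen defence, abscisic acid and drought, oxidative stress and xenobiotic detoxification, heat shock and unfolded proteins, anthocyanin and flavonoid synthesis, G2/M, DNA replication, DNA repair and damage signalling, the SOG1 branch of the damage response, DNA methylation and demethylation, senescence, auxin, iron deficiency, clock, and seed storage. Seed storage, with 11 genes at 0 to 13 reads per library, had fewer than 5 genes tested and was left out, leaving 18. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the 18 lists of a comparison. Genes were named if they had one of the 6 largest increases or 6 largest decreases of a comparison at 5 CPM or more in the higher group and, except for the interaction, moved the same way in every library; if they were among the 2 higher or 2 lower members of a list with the smallest p-values past the threshold; or if they were SMR5, SMR7, BRCA1, PARP2, CYCB1;1, TSO2, ROS1, MET1 or PR1. A further gene fixed in the same way is not reported here. The text gives a selection of the genes so named, and other genes are marked as chosen after their values were seen.

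The alternatives tried were DESeq2 1.42.0, RLE normalization, no filter on low counts, a threshold of 0.01, a fold of at least 2, only the compared groups in the fit, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Leaving out a library leaves its group with 1, which is then assumed to vary like the other groups. Leaving out the 19 ribosomal RNA repeat features, and assuming a coefficient of variation of 0.1 or 0.2 between plants with the 2 libraries of a group summed, were chosen after seeing the data. The replicate numbers were checked for pairing: correlations between residuals of libraries with the same number were -0.018 to 0.011, so the numbers were not used as pairs.

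The code was tested on simulated data with 200 changed genes among 20222. In the comparison of untreated genotypes it recovered 65.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold. The same shares were 77.6, 80.6 and 97.0% for genotypes under MMS, 71.6, 91.0 and 98.5% for MMS in wild type, 58.2, 79.1 and 98.5% for MMS in mem1, and 56.7, 70.1 and 95.5% for the interaction. Unchanged genes gave 8 to 15 false calls per comparison. The simulated spread was 1.45 times Poisson, that of the 2 libraries of a group, so these shares and false calls do not cover variation between plants. A list raised on purpose was called in all 5 comparisons, and of the 17 other lists 2 were called in untreated genotypes, 2 for MMS in wild type and 0 elsewhere. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.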

Results

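Messenger RNA of whole 10-day-old Arabidopsis thaliana seedlings was sequenced in 8 libraries. The seedlings were Col-0 wild type or the mutant mem1-1, written mem1 from here on, and were either left untreated or given 200 ppm MMS (methyl methanesulfonate), a chemical that methylates DNA bases. Each of the 4 combinations of genotype and treatment had 2 libraries. The libraries held 17880708 and 17729379 reads assigned to genes in untreated wild type, 14547814 and 15163017 in treated wild type, 12199568 and 13980145 in untreated mem1, and 13598804 and 14159069 in treated mem1. The labels do not say which gene carries the mem1-1 mutation and 0 genes in the reference table are named MEM1, so the mutated gene itself was not examined.

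Features of the ribosomal RNA repeats took 42.02 ± 0.142% of the reads in untreated wild type (mean ± SD, n = 2), 19.7 ± 0.101% in treated wild type, 29.0 ± 0.128% in untreated mem1 and 13.5 ± 0.0452% in treated mem1. The feature AT3G06365 alone took 9.83 to 29.8% of a library. Outside these repeats, a library of the 4 groups held on average 10322818, 11927978, 9292124 and 12001856 reads, in the same order. In a principal component analysis, the first component held 70% of the variance and separated treated from untreated libraries. The next 2 components held 13.7% and 9.02%.

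**Figure D1:**
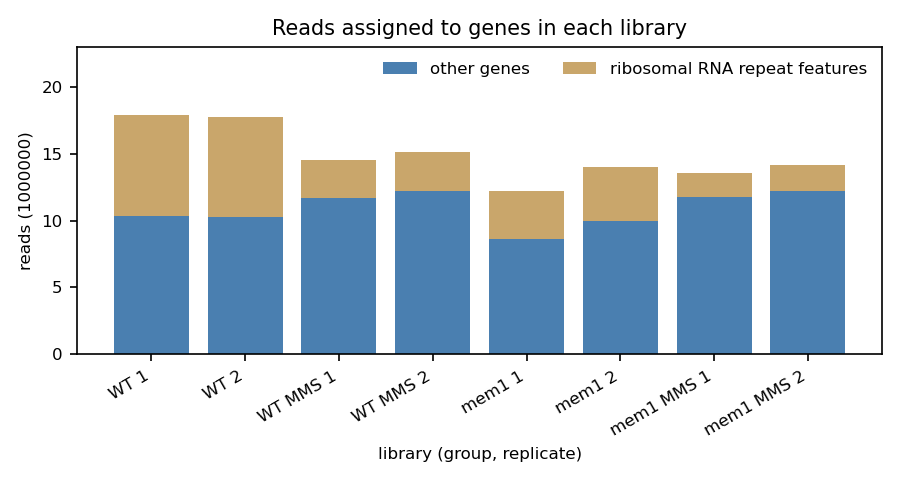
Reads per library in units of 1000000, stacked as reads of the ribosomal RNA repeat features and reads of all other genes, for the 2 libraries of each group. The repeat features took the largest share in untreated wild type (42.02%) and the smallest in treated mem1 (13.5%).

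The 2 libraries of each group were nearly alike. The variance between them was 1.49, 1.47, 1.42 and 1.42 times the counting (Poisson) variance in untreated wild type, treated wild type, untreated mem1 and treated mem1, and among genes above 3000 reads it was 1.66, 1.42, 1.37 and 1.57 times. Among genes above 3000 reads, the coefficient of variation beyond the variance ratio of genes with fewer reads had an upper 95% limit of at most 0.883%. Between untreated wild type and untreated mem1 the same ratio was 13.2, and between untreated and treated wild type it was 72.5. The p-values of single genes measure only the spread between these libraries, which may be technical, so small differences passed the tests. Camera at a preset correlation compares the genes of a list with the other genes tested. Its p-values rest on the number of genes and do not measure variation between plants. The labels do not say whether the 2 libraries of a group came from separate plants.

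The first comparison asks how mem1 seedlings differ from wild type without MMS. Untreated mem1 had lower levels of photosynthesis transcripts and higher levels of root marker transcripts. Lists of jasmonate responses (11 of 19 genes) and of salicylic acid and pathogen defence (13 of 19) were called lower in mem1, and that of abscisic acid and drought (11 of 18) higher, calls lost for all 3 with an estimated correlation (adjusted p = 0.0602 each). Of 20222 genes tested with edgeR, 7567 differed, 3619 higher and 3948 lower in mem1, and 1393 of them differed at least 2-fold (1067 higher, 326 lower). With an assumed coefficient of variation of 0.1 between plants 2248 genes differed, and with 0.2 the number was 338.

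All 24 photosynthesis genes were lower in untreated mem1, with a median log2 fold change of -0.62 (camera adjusted p = 1.43e-68, or 0.0129 with an estimated correlation). LHCB5 (AT4G10340), an antenna protein of photosystem II, measured 1790.0 ± 8.41 CPM (counts scaled to a library of 1000000; mean ± SD, n = 2) in wild type and 1141 ± 2.43 CPM in mem1, a log2 fold change of -0.65 ± 0.02 (SE). LHCB4.1 (AT5G01530) changed by -0.75 ± 0.01. RBCS1B (AT5G38430) and RBCS2B (AT5G38420), which encode the small subunit of Rubisco and share reads with near-identical copies, changed by -0.79 ± 0.01 and -0.71 ± 0.01. Of 17 root markers, 14 were higher in mem1 and 1 was lower (median 1.21, adjusted p = 4.07e-08, or 0.0408 with an estimated correlation). PIN2 (AT5G57090), an auxin efflux carrier of roots, rose from 14.8 ± 0.0654 to 37.4 ± 1.27 CPM (1.33 ± 0.11), and the phosphate transporter PHT1;1 (AT5G43350), which shares reads, from 75.05 ± 2.33 to 131 ± 6.13 CPM (0.81 ± 0.05). SCR (AT3G54220) was the lower root marker (-0.33 ± 0.08).

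In the jasmonate list 0 genes were higher and 11 of 19 lower in untreated mem1, or 12 adjusted over the list alone (median -0.49, camera adjusted p = 3.62e-06; adjusted p = 0.0602 with an estimated correlation). LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, fell from 549 ± 10.9 to 214 ± 10.2 CPM (-1.35 ± 0.02), and the storage protein VSP2 (AT5G24770) from 158 ± 0.678 to 88.9 ± 0.387 CPM (-0.83 ± 0.04). In the list of salicylic acid and pathogen defence 13 of 19 genes were lower, or 14 adjusted over the list alone, and 1 was higher (median -0.53, adjusted p = 1.82e-04; adjusted p = 0.0602 with an estimated correlation). PR1 (AT2G14610), a marker of salicylic acid responses, measured 3.88 ± 0.803 CPM in wild type and had 0 reads in both mem1 libraries, at least 16.9-fold lower against a floor of 3 counts per library (0.230 CPM; adjusted p = 4.16e-27). PR2 (AT3G57260) changed by -3.48 ± 0.32 and PAD3 (AT3G26830), an enzyme of camalexin synthesis, by -1.47 ± 0.13. In the list of abscisic acid and drought, 11 of 18 genes were higher and 2 lower, or 12 and 2 adjusted over the list alone, with a median of 0.53, or 0.49 with genes near 0 reads at their bound (adjusted p = 9.13e-04; adjusted p = 0.0602 with an estimated correlation). The dehydrin COR47 (AT1G20440) rose from 101.1 ± 2.09 to 204 ± 6.24 CPM (1.01 ± 0.04), and the lower genes were RD22 (AT5G25610, -0.38 ± 0.04) and COR15A (AT2G42540, -0.79 ± 0.20).

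Heat shock genes were called as a list with 8 of 15 higher and 2 lower, but their median of 0.26 and mean of -0.24 differed in sign (camera adjusted p = 0.0369, or 0.0508 without untreated mem1 replicate 1; adjusted p = 0.167 with an estimated correlation). Of the 12 lists not called in untreated mem1, the G2/M list had 7 of 21 genes higher and 0 lower (adjusted p = 0.0870) and the floral list 0 of 6 higher and 4 lower, or 5 adjusted over the list alone (median -1.14, adjusted p = 0.176); both were called without untreated wild type replicate 2 (adjusted p = 0.0474). In the DNA repair list 3 genes were higher and 3 lower of 31, or 2 and 1 adjusted over the list alone (adjusted p = 0.509). In the DNA damage list of genes under the transcription factor SOG1, 4 of 18 were higher and 1 lower, or 1 and 1 adjusted over the list alone (adjusted p = 0.353). Of these, TSO2 (AT3G27060) changed by -0.26 ± 0.07, and PARP2 (AT4G02390, adjusted p = 0.397), CYCB1;1 (AT4G37490, 0.244) and BRCA1 (AT4G21070, 0.137, or 0.0356 without untreated mem1 replicate 1) were not called. The methylation and demethylation list had 1 of 38 genes higher and 7 lower, or 1 and 5 adjusted over the list alone (adjusted p = 0.682). The DNA methyltransferase MET1 (AT5G49160) changed by -0.19 ± 0.06 (adjusted p = 0.00551, or 0.0715 without untreated wild type replicate 1 and 0.101 without untreated mem1 replicate 2). The demethylase ROS1 (AT2G36490) changed by -0.18 ± 0.06 (adjusted p = 0.00424, or 0.109 without untreated wild type replicate 2).

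The other lists not called in untreated mem1 were iron deficiency (0 of 7 higher, 2 lower, adjusted p = 0.145), DNA replication (6 of 16 higher, 1 lower, 0.176), anthocyanin (3 of 13 higher, 1 lower, 0.346), senescence (6 of 17 higher, 3 lower, 0.507), detoxification (10 of 29 higher, 12 lower, 0.685), auxin (1 of 8 higher, 3 lower, 0.690) and clock (3 of 16 higher, 4 lower, or 3 and 5 adjusted over the list alone, 0.987). Among single genes, AT5G35935 showed the largest increase the naming rule allowed, from 0.115 ± 0.0540 to 21.8 ± 0.967 CPM, a ratio of 189 with a counting interval of 64.4 to 920. CYP76G1 (AT3G52970) rose by 3.55 ± 0.49 and TIP2;3 (AT5G47450) by 3.11 ± 0.46 on the log2 scale. AT5G62080 fell from 6.14 ± 0.561 CPM to 0 reads, at least 26.8-fold, and SADHU3-2 (AT3G42658), of the Sadhu retroposon family, from 8.41 ± 0.187 to 0.388 ± 0.146 CPM (-4.43 ± 0.51).

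**Figure D2:**
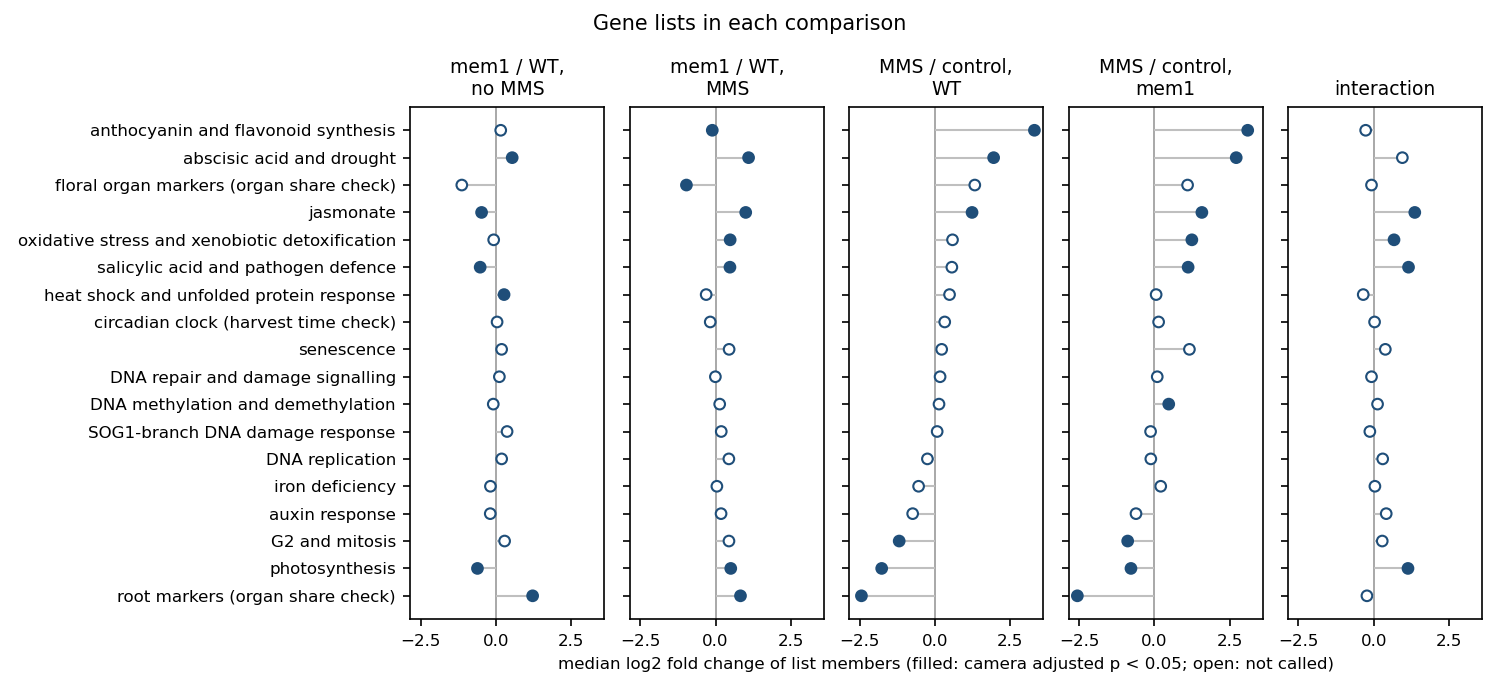
Median log2 fold change of each of the 18 gene lists in the 5 comparisons, with filled points where camera gave an adjusted p under 0.05. Photosynthesis stands below 0 in untreated mem1 (-0.62) and with MMS in wild type (-1.77), and above 0 in mem1 against wild type under MMS (0.50).

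The second comparison asks how wild type responds to MMS. Wild type seedlings given MMS had lower levels of photosynthesis transcripts and higher levels of transcripts of anthocyanin synthesis and of abscisic acid and drought responses. Root and cell division lists were called lower, calls lost with an estimated correlation (adjusted p = 0.0563 each). The jasmonate list was called higher with 10 of 19 genes higher and 5 lower, a call also lost with an estimated correlation (adjusted p = 0.189). DNA damage genes under SOG1 were not called as a list. Of the genes tested with edgeR, 13067 differed, 6562 higher and 6505 lower with MMS, and 4408 of them at least 2-fold (1932 higher, 2476 lower). With an assumed coefficient of variation of 0.1 there were 8446, and with 0.2 there were 3272.

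All 24 photosynthesis genes were lower with MMS in wild type (median -1.77, camera adjusted p = 2.36e-45, or 0.0176 with an estimated correlation). LHCB5 fell to 361 ± 7.63 CPM (-2.31 ± 0.02) and LHCB4.1 to 828 ± 2.98 CPM (-1.43 ± 0.01). Of the root markers 14 of 17 were lower and 0 higher (median -2.44, adjusted p = 4.68e-05; adjusted p = 0.0563 with an estimated correlation). PHT1;1 fell to 1.32 ± 0.400 CPM (-5.81 ± 0.22) and PIN2 to 2.69 ± 0.2 CPM (-2.46 ± 0.18). In the same libraries, all 6 floral markers were higher (median 1.32), although the list missed the threshold (adjusted p = 0.0515) and passed it without untreated wild type replicate 1 or either treated wild type library (0.0298 to 0.0451). The floral homeotic gene AP3 (AT3G54340) rose from 2.23 ± 0.971 to 8.76 ± 1.58 CPM (1.97 ± 0.24) and PI (AT5G20240) from 3.07 ± 0.317 to 8.42 ± 0.229 CPM (1.45 ± 0.22). In the G2/M list 0 of 21 genes were higher and 19 lower, or 20 adjusted over the list alone (median -1.19, adjusted p = 5.87e-04; adjusted p = 0.0563 with an estimated correlation). KN (AT1G08560), the syntaxin of cytokinesis, fell from 12.9 ± 1.21 to 4.41 ± 0.349 CPM (-1.55 ± 0.16).

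All 13 anthocyanin genes were higher with MMS in wild type (median 3.3, camera adjusted p = 1.29e-15, or 0.0169 with an estimated correlation). DFR (AT5G42800) rose from 13.9 ± 0.855 to 196 ± 1.69 CPM (3.82 ± 0.08) and chalcone synthase CHS (AT5G13930) from 269 ± 1.17 to 1060.0 ± 0.364 CPM (1.98 ± 0.02). In the list of abscisic acid and drought, 15 of 18 genes were higher (median 1.95, adjusted p = 1.33e-08, or 0.0176 with an estimated correlation), among them RAB18 (AT5G66400), which rose from 0.960 ± 0.0571 to 119 ± 0.458 CPM (6.94 ± 0.29). COR47 (-1.01 ± 0.05) and ERD10 (AT1G20450, -0.45 ± 0.07; shared reads) were its 2 lower genes. In the jasmonate list 10 of 19 genes were higher and 5 lower (median 1.23, adjusted p = 0.0398, or 0.0593 without untreated wild type replicate 1; adjusted p = 0.189 with an estimated correlation). VSP2 rose to 403 ± 0.840 CPM (1.35 ± 0.03) while LOX2 fell to 209.5 ± 2.60 CPM (-1.39 ± 0.02). The list of salicylic acid and pathogen defence, with 13 of 19 genes higher and 2 lower, missed the threshold (adjusted p = 0.0515), as did detoxification with 19 of 29 higher and 5 lower (0.0644). Both passed without untreated wild type replicate 2 or either treated wild type library (0.0408 to 0.0449 and 0.0435 to 0.0458). PR1 rose to 9.31 ± 1.24 CPM (1.26 ± 0.20) and PR5 (AT1G75040) fell from 8.64 ± 0.0795 to 2.88 ± 0.0741 CPM (-1.58 ± 0.19).

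Of the DNA damage genes under SOG1, 3 of 18 were higher and 3 lower in treated wild type, or 3 and 2 adjusted over the list alone (median 0.07, mean -0.10, camera adjusted p = 0.882). The higher genes were GMI1 (AT5G24280, 0.86 ± 0.13), AT4G32700 (0.91 ± 0.14) and AGO2 (AT1G31280, 0.42 ± 0.08, chosen here after its value was seen). The ribonucleotide reductase gene TSO2 fell from 55.6 ± 2.88 to 26.7 ± 1.44 CPM (-1.06 ± 0.07). CYCB1;1 changed by -0.60 ± 0.27 (adjusted p = 0.0361, or 0.252 without untreated wild type replicate 1, 0.300 without treated wild type replicate 2 and 0.124 in DESeq2), and NAC044 (AT3G01600) by -1.84 ± 0.76 (adjusted p = 0.0147, or 0.307 without untreated wild type replicate 1, 0.144 without treated wild type replicate 1 and 0.0691 in DESeq2). BRCA1 (adjusted p = 0.866) and PARP2 (0.545) were not called, at 3.67 and 4.29 CPM in treated wild type. SMR5 (AT1G07500) had 0 reads in every library, with 100% of its exon length overlapped by another gene, and SMR7 (AT3G27630) had 1 to 8 reads per library, so neither was tested. The DNA repair list had 11 of 31 genes higher and 8 lower (adjusted p = 0.233). The damage kinase gene ATM (AT3G48190) rose from 33.2 ± 0.989 to 79.1 ± 0.282 CPM (1.25 ± 0.07) and the translesion polymerase gene REV1 (AT5G44750) from 51.4 ± 0.693 to 103 ± 0.999 CPM (1.01 ± 0.06), while the photolyase gene UVR3 (AT3G15620) fell by 1.66 on the log2 scale.

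The methylation list had 18 of 38 genes higher and 7 lower with MMS in wild type (camera adjusted p = 0.233). MET1 fell from 68.5 ± 1.81 to 34.2 ± 0.339 CPM (-1.003 ± 0.06), and ROS1 rose from 69.6 ± 3.08 to 91.7 ± 2.49 CPM (0.40 ± 0.05). Lists not called were also clock (8 of 16 higher, 2 lower, adjusted p = 0.0924), heat shock (8 of 15 higher, 2 lower, 0.172), iron (1 of 7 higher, 4 lower, 0.220), replication (2 of 16 higher, 8 lower, 0.474), senescence (7 of 17 higher, 4 lower, 0.6) and auxin (3 of 8 higher, 5 lower, 0.905). In the clock list CCA1 (AT2G46830) rose from 2.15 ± 0.223 to 20.07 ± 0.522 CPM (3.22 ± 0.22) and LUX (AT3G46640) changed by -1.05 ± 0.12. The list was fixed as a check of harvest time. Its genes moved both ways, which a test for a shared direction can miss, so it does not settle whether harvest times differed. The largest increases allowed by the naming rule included AT1G47980, from 0 reads to 39.1 ± 0.365 CPM (at least 170-fold), and the pollen wall genes MS2 (AT3G11980, at least 142-fold) and CYP703A2 (AT1G01280, at least 54.2-fold). LTP4 (AT5G59310) rose from 0.959 ± 0.269 to 1082 CPM (10.13 ± 0.26). AT1G31690 fell at least 151-fold, from 25.6 ± 0.197 CPM to 0 reads.

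The third comparison asks how mem1 responds to MMS. Treated mem1 had lower levels of photosynthesis, root and cell division transcripts than untreated mem1. Anthocyanin, jasmonate, abscisic acid, salicylic acid and detoxification transcripts were all higher as lists, and so were genes of DNA methylation and demethylation. Of the genes tested with edgeR, 12982 differed, 6526 higher and 6456 lower with MMS, and 4544 of them at least 2-fold (2049 higher, 2495 lower). With an assumed coefficient of variation of 0.1 there were 8415, and with 0.2 there were 3584. The 9 lists called were also called with an estimated correlation (adjusted p = 0.0143 to 0.0430) and with any library left out. Leaving out libraries may not cover variation between plants, and no list was tested with an assumed coefficient of variation.

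Of the photosynthesis genes 21 of 24 were lower with MMS in mem1 (median -0.78, camera adjusted p = 6.41e-19). LHCB5 fell to 620.2 ± 6.64 CPM (-0.88 ± 0.02) and LHCB4.1 to 1125 ± 13.6 CPM (-0.23 ± 0.01), while LHCB2.1 (AT2G05100, 1.59 ± 0.10) and LHCB2.2 (AT2G05070, 1.98 ± 0.11), which share reads, were higher. Of the root markers 15 of 17 were lower (median -2.56, adjusted p = 2.42e-07), among them PIN2, which fell to 5.79 ± 0.895 CPM (-2.69 ± 0.14), and SCR was higher (0.50 ± 0.08). Of the 6 floral markers 5 were higher, or 6 adjusted over the list alone (adjusted p = 0.276), and AP3 rose to 3.78 ± 0.599 CPM (2.16 ± 0.37). In the G2/M list 18 of 21 genes were lower, or 19 adjusted over the list alone, and 0 higher (median -0.89, adjusted p = 9.68e-04), with KN at -1.54 ± 0.15 and the mitotic cyclin CYCB1;2 (AT5G06150) at -1.16 ± 0.14.

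Of 19 jasmonate genes 18 were higher with MMS in mem1 and 0 lower (median 1.58, camera adjusted p = 1.75e-13). LOX2 rose to 2023 ± 1.35 CPM (3.24 ± 0.02) and VSP2 to 1501 ± 5.68 CPM (4.08 ± 0.03). The defensin gene PDF1.2 (AT5G44420) rose from 0.142 ± 0.201 to 393 ± 10.0 CPM (11.26 ± 0.71), and its near-identical copy PDF1.2c (AT5G44430) from 0 reads to 383 ± 0.133 CPM, at least 1670-fold. Of 19 genes of salicylic acid and pathogen defence 15 were higher and 0 lower (median 1.12, adjusted p = 5.78e-08). PR1 rose from 0 reads to 9.11 ± 0.661 CPM, at least 39.7-fold, PR2 from 0.907 ± 0.126 to 62.8 ± 2.07 CPM (6.09 ± 0.30) and PAD3 from 6.81 ± 0.0282 to 124 ± 0.531 CPM (4.18 ± 0.12). Of 29 detoxification genes 21 were higher and 5 lower, or 22 and 5 adjusted over the list alone (median 1.25, adjusted p = 8.27e-05). The glutathione transferase genes GSTF6 (AT1G02930) and GSTF7 (AT1G02920), a close pair, both changed by 3.46 (SE 0.06 and 0.09), and GSTU22 (AT1G78340) changed by -3.63 ± 0.29.

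In the list of abscisic acid and drought 14 of 18 genes were higher with MMS in mem1 and 2 lower (median 2.72, camera adjusted p = 8.30e-12). P5CS1 (AT2G39800), an enzyme of proline synthesis, rose from 54.9 ± 0.461 to 450.4 ± 10.6 CPM (3.04 ± 0.04), and COR47 (-2.02 ± 0.05) and LTI30 (AT3G50970, -1.43 ± 0.16) were lower. All 13 anthocyanin genes were higher (median 3.10, adjusted p = 1.75e-13), with DFR at 97.9 ± 3.99 CPM (2.66 ± 0.08). Of 38 genes of DNA methylation and demethylation 23 were higher and 2 lower, or 23 and 3 adjusted over the list alone (median 0.48, adjusted p = 0.00349). NRPD2 (AT3G23780), a subunit of RNA polymerases IV and V with shared reads, changed by 1.202 ± 0.06 and MBD9 (AT3G01460) by 1.04 ± 0.06. ROS1 rose from 61.2 ± 0.113 to 111 ± 0.650 CPM (0.86 ± 0.05) and MET1 from 60.2 ± 2.16 to 85.8 ± 1.70 CPM (0.51 ± 0.06).

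Of the DNA damage genes under SOG1, 4 of 18 were higher and 5 lower in treated mem1, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.964, with test, median and mean of differing sign). GMI1 rose from 7.98 ± 0.518 to 25.02 ± 2.01 CPM (1.65 ± 0.13). CYCB1;1 fell (-1.29 ± 0.28, adjusted p = 3.93e-06). PARP2 changed by -0.70 ± 0.24 (adjusted p = 0.00609, or 0.422 without untreated mem1 replicate 2). TSO2 (adjusted p = 0.978) and BRCA1 (0.815) were not called. The DNA repair list had 10 of 31 genes higher and 7 lower (adjusted p = 0.745), with ATM at 1.28 ± 0.06 and REV3 (AT1G67500) at 1.298 ± 0.09. Further lists not called were senescence (10 of 17 higher, 4 lower, or 11 and 4 adjusted over the list alone; median 1.17, or 0.60 with bounds; adjusted p = 0.418), clock (5 of 16 higher, 5 lower, 0.517), heat shock (6 of 15 higher, 2 lower, 0.694), auxin (2 of 8 higher, 3 lower, 0.835), replication (4 of 16 higher, 6 lower, 0.964) and iron (1 of 7 higher, 2 lower, 0.964, again of differing sign). NATA1 (AT2G39030) rose from 0.0356 ± 0.0503 to 247 ± 0.474 CPM, in summed reads a ratio of 6480 with a counting interval of 1160 to 256000. CYP76G1 fell to 0 reads, at least 31.4-fold.

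The fourth comparison asks how mem1 differs from wild type when both are given MMS. Under MMS mem1 had higher levels of photosynthesis, jasmonate, abscisic acid and detoxification transcripts than wild type. The list of salicylic acid and pathogen defence was called higher too, a call lost with an estimated correlation (adjusted p = 0.0720). Root markers (9 of 17) were called higher and floral markers (5 of 6) lower, calls lost with an estimated correlation (adjusted p = 0.202 each) and with some single libraries left out. Of the genes tested with edgeR, 10464 differed, 5742 higher and 4722 lower in mem1, and 1876 of them at least 2-fold (1165 higher, 711 lower). With an assumed coefficient of variation of 0.1 there were 4356, and with 0.2 there were 628.

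Of the photosynthesis genes 20 of 24 were higher in treated mem1 and 3 lower (median 0.50, camera adjusted p = 2.89e-16, or 0.0297 with an estimated correlation). LHCB5 differed by 0.78 ± 0.02, LHCB4.1 by 0.44 ± 0.02 and PSAF (AT1G31330) by 0.92 ± 0.02. The lower genes encode the small subunit of Rubisco and share reads: RBCS1B (-0.21 ± 0.01), RBCS2B (-0.46 ± 0.01) and RBCS1A (AT1G67090, -0.03, chosen here after its value was seen). In the same libraries 9 of 17 root markers were higher and 0 lower (median 0.83, adjusted p = 0.0472; adjusted p = 0.202 with an estimated correlation). That call was lost without treated wild type replicate 2 (0.0550), treated mem1 replicate 1 (0.0523) or 2 (0.1), or untreated mem1 replicate 2 (0.103). PHT1;1 stood at 10.1 ± 0.363 CPM in mem1 (2.92 ± 0.23). Of the 6 floral markers 5 were lower, or 6 adjusted over the list alone (median -0.97, adjusted p = 0.0265, or 0.0548 without treated mem1 replicate 1; adjusted p = 0.202 with an estimated correlation), with PI at -1.63 ± 0.22.

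Of 19 jasmonate genes 13 were higher in treated mem1 and 2 lower (median 1.00, camera adjusted p = 6.22e-11, or 0.0297 with an estimated correlation). LOX2 differed by 3.27 ± 0.02, VSP2 by 1.90 ± 0.02 and TAT3 (AT2G24850) by 3.88 ± 0.22, while JAZ6 (AT1G72450, -0.49 ± 0.08) and ORA59 (AT1G06160, -0.54 ± 0.15) were lower. In the list of abscisic acid and drought 13 of 18 genes were higher and 3 lower (median 1.1, adjusted p = 6.22e-11, or 0.0297 with an estimated correlation). The phosphatase gene HAI1 (AT5G59220) measured 27.7 ± 1.86 CPM in wild type and 182 ± 0.726 CPM in mem1 (2.71 ± 0.06), and RAB18 was lower (-0.60 ± 0.05). Of 29 detoxification genes 18 were higher and 1 lower (median 0.48, adjusted p = 4.15e-05, or 0.0333 with an estimated correlation), with GSTF6 at 0.90 ± 0.03 and the lower gene GSTU3 (AT2G29470) at -1.94 ± 0.40. Of 19 genes of salicylic acid and pathogen defence 11 were higher and 1 lower (median 0.48, adjusted p = 7.96e-04; adjusted p = 0.0720 with an estimated correlation). PR2 differed by 1.91 ± 0.09 and PR5 by 3.63 ± 0.17, and PR1 was not called (adjusted p = 0.878).

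In the anthocyanin list 2 of 13 genes were higher in treated mem1 and 6 lower, or 3 and 6 adjusted over the list alone (median -0.11, camera adjusted p = 0.0472; adjusted p = 0.196 with an estimated correlation). Leaving out either library of untreated wild type, treated wild type or treated mem1 ended that call (0.0508 to 0.0564), as did the replicate number as a block (0.0519). DFR stood at -1.004 ± 0.04 and LDOX (AT4G22880) at -0.65 ± 0.05. The methylation list had 14 of 38 genes higher and 4 lower (adjusted p = 0.0776), with MET1 at 34.2 ± 0.339 CPM in wild type and 85.8 ± 1.70 CPM in mem1 (1.33 ± 0.06), ROS1 at 0.28 ± 0.04 and AGO4 (AT2G27040) at 0.88 ± 0.05. Replication genes, with 11 of 16 higher and 1 lower, missed the threshold (adjusted p = 0.0713) and passed it without either untreated wild type library or treated wild type replicate 1 (0.0461 to 0.0483). The DNA repair list had 9 of 31 genes higher and 9 lower (adjusted p = 0.517), with REV1 at -0.66 ± 0.05.

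The list under SOG1 had 4 of 18 genes higher and 1 lower in treated mem1 (camera adjusted p = 0.517). TSO2 differed by 0.80 ± 0.07 and GMI1 by 0.60 ± 0.10. BRCA1 differed by 0.53 ± 0.21 (adjusted p = 0.0226), a call lost without any of the treated libraries (0.0506 to 0.118) and in DESeq2 (0.118). PARP2 was lower (-0.60 ± 0.23, adjusted p = 0.0210), a call lost without treated wild type replicate 2 or either treated mem1 library (0.0700 to 0.12) and in DESeq2 (0.105). CYCB1;1 (adjusted p = 0.364) was not called. Further lists not called were G2/M (9 of 21 higher, 0 lower, adjusted p = 0.159), clock (2 of 16 higher, 5 lower, 0.211), senescence (10 of 17 higher, 5 lower, 0.267), auxin (0 of 8 higher, 2 lower, 0.516), heat shock (2 of 15 higher, 7 lower, 0.650) and iron (2 of 7 higher, 2 lower, 0.904). AT5G35935 had 0 reads in treated wild type and 25.9 ± 1.27 CPM in treated mem1, at least 152-fold higher. The ubiquitin ligase gene PUB19 (AT1G60190) measured 5.99 ± 0.461 and 109 ± 1.21 CPM (4.18 ± 0.11). AT1G67105 was lower, at 7.44 ± 0.342 CPM in wild type against 0.126 CPM in mem1 (-5.79 ± 0.77).

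The fifth comparison asks whether MMS acted differently in mem1 and in wild type, as an interaction of genotype and treatment. The photosynthesis decrease with MMS was smaller in mem1, and the effect of MMS on jasmonate, salicylic acid and detoxification genes was more positive there. Each interaction also takes in the untreated difference of mem1 from wild type. Its median was -0.62 for photosynthesis, -0.49 for jasmonate, -0.53 for salicylic acid and -0.08 for detoxification. Under MMS the medians of mem1 against wild type were 0.50, 1.00, 0.48 and 0.48. Of the genes tested with edgeR, 8957 had an interaction, 5069 positive (MMS effect more positive in mem1) and 3888 negative, and 2358 of them were at least 2-fold (1279 positive, 1079 negative). With an assumed coefficient of variation of 0.1 there were 2672, and with 0.2 there were 228.

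All 24 photosynthesis genes had a positive interaction (median 1.14, camera adjusted p = 5.09e-58, or 0.0155 with an estimated correlation), with LHCB5 at 1.43 ± 0.03 and LHCB4.1 at 1.19 ± 0.02. Of 19 jasmonate genes 15 were positive and 1 negative (median 1.36, adjusted p = 3.37e-11, or 0.0372 with an estimated correlation). LOX2 fell with MMS in wild type and rose in mem1, an interaction of 4.63 ± 0.03, and VSP2 stood at 2.73 ± 0.04. The negative gene was JAZ6 (-0.45 ± 0.14), which was not called without untreated mem1 replicate 2 (adjusted p = 0.0734). Of 19 genes of salicylic acid and pathogen defence 15 were positive and 0 negative, with a median of 1.16, or 1.13 without genes at 0 reads in a group (adjusted p = 2.75e-06, or 0.0372 with an estimated correlation). PR2 stood at 5.39 ± 0.33 and PAD3 at 2.65 ± 0.14, and PR1 passed the test (adjusted p = 2.89e-23). For PR1 the treated genotypes did not differ by the test, and the interaction came from its lower level in untreated mem1. Of 29 detoxification genes 18 were positive and 3 negative, or 18 and 4 adjusted over the list alone (median 0.67, adjusted p = 3.00e-04, or 0.0483 with an estimated correlation), with GSTF7 at 2.73 ± 0.10. These 4 lists were called with any library left out, which may not cover variation between plants. No list was tested with an assumed coefficient of variation.

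The list under SOG1 had 3 of 18 genes with a positive interaction and 1 negative (camera adjusted p = 0.861). GMI1 stood at 0.79 ± 0.18 and TSO2 at 1.06 ± 0.10. The negative gene was PARP2 (-0.86 ± 0.33, adjusted p = 0.0222), a call lost in DESeq2 (0.118) and without untreated wild type replicate 1, treated wild type replicate 2, untreated mem1 replicate 2 or treated mem1 replicate 1 (0.0637 to 0.366). BRCA1 (adjusted p = 0.805) and CYCB1;1 (0.132) were not called. MET1 fell with MMS in wild type and rose in mem1 (1.52 ± 0.08), and ROS1 rose more in mem1 (0.47 ± 0.07), while the methylation list with 14 of 38 positive and 2 negative was not called (adjusted p = 0.130). Other lists not called were abscisic acid and drought (11 of 18 positive, 5 negative, adjusted p = 0.129), anthocyanin (2 of 13 positive, 5 negative, 0.129), DNA repair (4 of 31 positive, 6 negative, or 2 and 5 adjusted over the list alone, 0.432), heat shock (3 of 15 positive, 6 negative, 0.432), iron (2 of 7 positive, 0 negative, 0.440), clock (2 of 16 positive, 4 negative, 0.480) and senescence (5 of 17 positive, 2 negative, 0.657). The same held for replication (7 of 16 positive, 3 negative, 0.737), auxin (3 of 8 positive, 2 negative, or 3 and 3 adjusted over the list alone, 0.769), floral markers (0 positive, 0 negative of 6, 0.769), G2/M (3 of 21 positive, 1 negative, or 3 and 0 adjusted over the list alone, 0.861) and root markers (4 of 17 positive, 2 negative, 0.884).

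**Figure D3:**
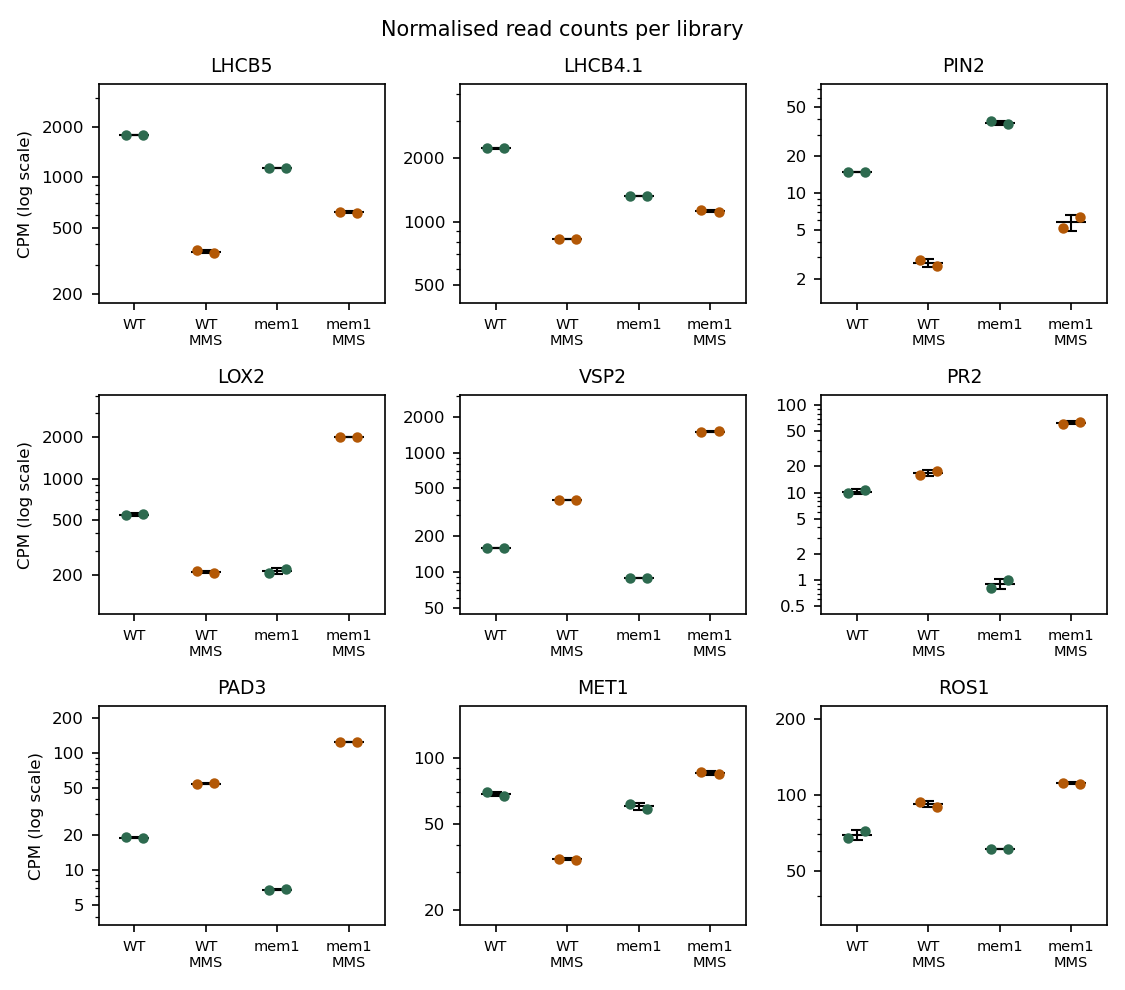
CPM on a log axis for 9 genes in wild type (WT) and mem1, untreated and with MMS; points are libraries and bars the mean ± SD of 2. LOX2 measured 548.6 CPM in untreated wild type and 209.5 CPM in treated wild type, against 214 CPM in untreated and 2023 CPM in treated mem1.

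The responses to MMS in wild type and in mem1, which share no library, were then compared across the 20222 genes. Their log2 fold changes had a Pearson correlation of 0.74 and a Spearman correlation of 0.65 across genes, which are not independent replicates. Without a filter on low counts the Pearson correlation was 0.494. Both genotypes called 4114 genes higher and 4213 lower, where independent calls would give 2118 and 2077. Another 439 genes were higher in wild type and lower in mem1, and 809 lower in wild type and higher in mem1, where independent calls would give 2095 and 2099. Of the 9575 genes called in both, 4770 also differed between genotypes by the interaction test.

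The effect of mem1 without MMS was compared with the effect of MMS in wild type, to ask whether the untreated mutant resembles treated wild type. The Pearson correlation across genes was -0.12 and the Spearman correlation 0.06. Both effects are measured against the same 2 untreated wild type libraries. The noise of those libraries alone gave a mean covariance of 0.0568 in 20 simulations without any effect, and the observed covariance was -0.0938. Without a filter on low counts the Pearson correlation was 0.156, and without untreated wild type replicate 1 or 2 it was 0.0456 or 0.0532. Higher in both were 1201 genes (1174 if independent) and lower in both 2140 (1270), while 1354 were higher in mem1 and lower with MMS (1164) and 1003 lower in mem1 and higher with MMS (1281).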

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

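Of the tests of explanations given here, the test on reads shared between near-identical genes was written before its result was seen, and the tests on a scale difference and on green tissue were chosen after.

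The response to MMS differed between mem1 and wild type by a test of the difference itself, the interaction in edgeR, for 8957 genes and 4 gene lists. The median interaction log2 fold change was 1.36 for jasmonate, 1.16 for salicylic acid and pathogen defence, 1.14 for photosynthesis and 0.67 for detoxification. Among jasmonate genes LOX2 stood at 4.63, VSP2 at 2.73 and JAZ6 at -0.45 (JAZ6 was not called without untreated mem1 replicate 2, adjusted p = 0.0734). Among defence genes PR2 stood at 5.39 and PAD3 at 2.65, and PR1 passed with an adjusted p of 2.89e-23. PR1 was not called between the treated genotypes, so its interaction came from its lower level in untreated mem1. In the detoxification list GSTF6 stood at 2.07, GSTF7 at 2.73, GSTU25 at -1.05 and GSTU1 at -1.12. In the photosynthesis list LHCB5 stood at 1.43 and LHCB4.1 at 1.19.

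A scale difference between libraries, as the whole cause, would move all members of these 4 lists alike. The interactions of their 43 members with whole counts and at least 5 CPM in every group ran from -1.12 to 4.63, with a standard deviation of 1.065, which argues against it. Reads shared as fractions between near-identical genes were tested as the whole cause too. Of 76 members with whole counts in all libraries, out of 91, 57 were called higher in the interaction and 4 lower. Most members had whole counts and most were called higher, so this test could hardly have come out otherwise, and no verdict is drawn from it. The values show only that these 57 calls lie in genes without fractions. Sharing that leaves whole counts was not tested. For photosynthesis, a larger share of green tissue in treated mem1 as the whole cause would move the genes alike. The 24 genes moved apart, from 0.25 to 2.41 with a standard deviation of 0.6031 (bound 0.5). Some of them have fractional counts and are uncertain. Among the 11 with whole counts the standard deviation was 0.4223, under that bound, so the test cannot decide. The lowest and highest of these were LHCA1 (0.71 ± 0.04) and LHCB3 (2.08 ± 0.09). All 24 genes were also lower in untreated mem1 (median -0.62), and that difference enters the interaction. A share in treated mem1 cannot give it, which argues against such a share as the whole cause. As part of the cause such a share stays open. The interaction shows that the response differed between these samples, and whether the mem1-1 mutation is the reason stays open.

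The same test called single genes of DNA methylation and damage, while the methylation list (adjusted p = 0.130) and the list under SOG1 (0.861) were not called. MET1 stood at 1.52, ROS1 at 0.47, TSO2 at 1.06 and PARP2 at -0.86. The PARP2 call was lost in DESeq2 (adjusted p = 0.118) and without untreated wild type replicate 1, treated wild type replicate 2, untreated mem1 replicate 2 or treated mem1 replicate 1 (0.0637 to 0.366).

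Genes with the largest interactions included some at 0 to 3 reads in a group, for which CPM and adjusted p are given without a fold. In untreated and treated wild type and untreated and treated mem1, in that order, PDF1.2c measured 0.807, 52.8, 0 and 383 CPM (adjusted p = 7.54e-20). PDF1.2b measured 0.462, 3.96, 0 and 13.7 CPM (1.06e-07, or 0.106 without untreated wild type replicate 2). NATA1 measured 1.15, 32.5, 0.0356 and 247 CPM (3.11e-26), and MEE48 2.30, 16.6, 0 and 16.3 CPM (2.64e-16). AT3G44006 measured 1.27, 5.50, 0 and 5.02 CPM (3.31e-08), and AT3G06070 6.99, 0.738, 7.45 and 0.0309 CPM (1.04e-05). CYP76G1 measured 0.499, 0.0566, 5.95 and 0 CPM (0.0130, or 0.0546 and 0.0529 without treated wild type replicate 1 and 2). The interaction log2 fold change was -6.76 for AT1G67105, -4.23 for AT1G72416, -3.90 for AT5G19190 and -3.77 for AT1G52820.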

How the results depend on the processing

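Leaving out the ribosomal RNA repeat features and assuming a coefficient of variation between plants were chosen after seeing the data; the other alternatives were planned. No called gene or list changed direction, except where fry is named here.

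The number of genes called moved by less than 1.5 times with RLE, no filter on low counts, a threshold of 0.01, DESeq2 (5228, 7920, 11113, 11135 and 6573 for untreated genotypes, genotypes under MMS, MMS in wild type, MMS in mem1 and the interaction), only the compared groups, or the repeat features left out. It did the same with the replicate block (7482, 10398, 13015, 12917 and 8893), although the numbers do not pair the libraries. These are totals. By direction, DESeq2 called 2232 genes higher and 2996 lower in untreated mem1, and 4077 positive and 2496 negative in the interaction. With 1 library left out the counts were 5872 to 7517, 8743 to 10615, 11764 to 13129, 11563 to 13226 and 7870 to 8086. At a fold of at least 2 the counts were 1393, 1876, 4408, 4544 and 2358. With an assumed coefficient of variation of 0.1 they were 2248, 4356, 8446, 8415 and 2672, and with 0.2 they were 338, 628, 3272, 3584 and 228. That setting also sums the 2 libraries of a group, and the cause was not tested. Of the calls of at least 2-fold, 94.0, 97.8, 99.98, 99.98 and 87.6% were kept at 0.1 and 24.3, 33.5, 74.2, 78.9 and 9.67% at 0.2.

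Of 18 lists, camera called 2, 4, 3, 9 and 4 with an estimated correlation, and fry, which does not compare a list with other genes, called 14, 16, 15, 14 and 12. Some calls were lost although the estimated correlation lay under the preset 0.01. In untreated genotypes it was -0.009 for abscisic acid and -0.017 for salicylic acid and pathogen defence. A higher correlation does not account for such losses. With an estimated correlation, camera takes its p-values from the few degrees of freedom that 8 libraries leave, not from the number of genes. That change can end a call without a higher correlation, and it was not tested apart. Lists were not tested with an assumed coefficient of variation between plants. With 1 library left out camera called 5 to 8, 5 to 8, 6 to 9, 9 and 4. Heat shock genes under MMS, not called and lower by camera, were higher by fry (adjusted p = 0.00362); the cause was not tested. Of 90 list results 1 was lost with the replicate block (anthocyanin under MMS, adjusted p = 0.0519), and leaving out libraries lost 13 calls and gave 14.

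Of 383 results for single genes, 25 lost their call in DESeq2, 3 without a filter, 95 and 208 with the assumed 0.1 and 0.2, and 0 with RLE, the replicate block or the repeat features left out. Over 8 libraries left out, 104 calls were lost and 1 was gained.

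The correlation of the 2 MMS responses was 0.494 without a filter, 0.756 for genes of at least 5 CPM and 0.6998 to 0.7234 with 1 library left out. That of the mem1 and MMS effects was 0.156 without a filter, -0.0131 for genes of at least 5 CPM and -0.124 to 0.0532 with 1 library left out, positive without untreated wild type replicate 1 (0.0456) or 2 (0.0532); the cause was not tested. Depth limits genes near the floor of 3 counts per library, where a group at 0 gives a bound alone. The test on transposable element genes was not run.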

Other observations

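The tests of the floral list and of LHY, SAG13 and OPT3 were planned. The other tests on anther and floral genes and on shares of root and flower buds were chosen after the results were seen. So was the test on genes changed at least 2-fold in mem1.

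Pollen wall genes were among the largest increases with MMS, and 10 anther and tapetum genes were listed after that was seen, so their counts describe these libraries and test nothing. Of the 10, 9 were called higher with MMS in wild type and 10 in mem1. Untreated, 2 of them had 0 reads in wild type and 4 in mem1, so no median fold change is given. ACOS5 measured 2.11 CPM in untreated and 21.7 CPM in treated wild type, and 0.142 and 8.61 CPM in mem1. LTP12 had 0 reads in both untreated groups and measured 6.25 CPM in treated wild type and 3.69 CPM in treated mem1. In mem1 against wild type, 5 of the 10 were lower untreated, and 8 were lower and 1 higher under MMS. The interaction was positive for 4 and negative for 0.

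Genes at least 2-fold higher in untreated mem1 were often lower with MMS in wild type. Of these 1067 genes, 568 (53.2%) were lower with MMS, where 343 would be if independent, and 146 (13.7%) were higher, where 346 would be. Of the 326 genes at least 2-fold lower in untreated mem1, 150 (46.0%) were higher with MMS (106 if independent) and 73 (22.4%) lower (105). The shared untreated wild type libraries alone give the opposite direction. Across all genes, the mem1 effect without MMS and under MMS, which share no library, had a Pearson correlation of 0.132. Higher in both were 1261 genes (1028 if independent) and lower in both 1131 (922), while 1583 were lower untreated and higher under MMS (1121) and 635 higher untreated and lower under MMS (845).

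In untreated mem1 14 of 17 root markers were higher and all 24 photosynthesis genes lower. The 24 changes lay between -0.89 and -0.42, with a standard deviation of 0.118, which is consistent with a larger share of root in the untreated mem1 samples. The root markers moved apart, from SCR at -0.33 ± 0.08 over PIN2 at 1.33 ± 0.11 to TIP2;3 at 3.11 ± 0.46, with a standard deviation of 0.803. This spread cannot decide on that share as the whole cause, since markers partly expressed outside roots would move by other amounts. A larger share of root is argued against as the whole cause under MMS, where 20 of 24 photosynthesis genes were higher in mem1 with changes from -0.46 to 1.99 (standard deviation 0.663). An effect of the genotype on expression within tissues stays open and was not tested.

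Flower buds in the treated wild type samples may account for the anther and floral genes there, since 10 of 11 floral and carpel markers outside the anther list were also called higher. These are all 6 of the floral list fixed in advance (adjusted p = 0.0515 for the list) and 4 of 5 chosen later, such as CRC (1.58 and 5.69 CPM) and SEP2 (1.61 and 4.91 CPM), which as a list were not called either (adjusted p = 0.0901). In treated mem1 7 of the 11 were called higher and 0 lower: 5 of the 6 fixed in advance (median 1.104, adjusted p = 0.276 for the list) and 2 of the 5 (adjusted p = 0.451). That share lies between the bounds set, at a few CPM. The interaction was called for 0 of the 6 and was negative for 1 of the 5 (camera adjusted p = 0.769 and 0.481). The 10 called in wild type and 7 in mem1 thus do not show that the response differed. Flower buds in treated mem1 cannot be told apart from anther genes rising without them. Activation of these genes in other tissues by MMS stays open and was not tested. The labels name seedlings of 10 days and no flowers.

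The circadian clock gene LHY rose with MMS from 25.1 ± 2.08 to 57.9 ± 0.234 CPM in wild type and from 19.2 ± 0.371 to 62.1 ± 1.61 CPM in mem1, and the labels do not give the time of harvest. The senescence gene SAG13 rose from 4.49 ± 0.0412 to 58.8 ± 1.37 CPM in wild type and from 0.347 ± 0.0881 to 136 ± 5.39 CPM in mem1, an interaction of 4.89 ± 0.51 on the log2 scale. The iron transporter gene OPT3 fell with MMS in wild type (-0.54) and rose in mem1 (0.48), an interaction of 1.03 ± 0.05.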
